A study of Mus musculus with 4 samples.

How the data were processed

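Single-cell RNA libraries were made from sorted thymic iNKT cells of BALB/c and B6 mice with a 10x Genomics 5' kit, per the labels' protocols, with 2 libraries per strain. The authors deposited, for each library, a matrix of UMI counts per gene and cell barcode, which are whole numbers and not normalized. UMI counts are numbers of distinct tagged molecules, so PCR copies of a molecule count once. The submitters' processing notes name Cell Ranger 7.1.0 and the genome build mm10. The file headers give Cell Ranger 6.0.0 for BALB/c 1, BALB/c 2 and B6 1, and 7.1.0 for B6 2. Whether reads within introns were counted is not given in the sources used here, and the default of Cell Ranger changed in this respect between these major versions. Each file listed 32285 genes, of which 32235 (99.9%) were matched by identifier to GENCODE vM21 on GRCm38 for positions and intron lengths.

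Barcodes with under 500 genes, under 1000 UMIs or over 10% mitochondrial UMIs were removed. Scrublet, as built into scanpy, was used to rank all deposited barcodes of a library by doublet score. Those with the highest scores were removed, as many as 0.8% per 1000 barcodes of the library. This marked 33, 34, 50 and 758 barcodes in BALB/c 1, BALB/c 2, B6 1 and B6 2, and some of those in BALB/c 1 and B6 2 had also failed the filters. The number marked is fixed by that rate and is not a measured doublet rate. The kept cells of the 4 libraries were clustered together (2000 variable genes ranked within each library, 30 principal components, 15 neighbours, Leiden resolution 1.0). TCR and immunoglobulin segments, H2, Klra, mitochondrial, ribosomal, sex-linked and cell cycle genes were left out of the variable genes.

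Clusters were named from marker lists fixed before the data were examined, but the scoring rule was not fixed then. It was revised 2 times after class shares had been seen, so 3 rules were tried. The first used all markers and asked for a mean log2 fold of at least 0.4 and at least 3 markers above 0.5. The fold was taken over the average of the other clusters' means, in which each cluster weighs the same whatever its size. The second left out Klrb1c and Ly6c2, which are known to be polymorphic between strains, and asked for a mean of at least 0.4 and 50% of the markers. The third, used here, lowered these to 0.3 and 40%, because the second left unnamed a large BALB/c cluster that was high in Il4 and Zbtb16 when all deposited barcodes were used. Differential tests had also been looked at before the effect of the first 2 rules was computed; the rule and the models were not changed after that. Rules 2 and 3 gave the same cells of each class in the clustering used, and rule 1 differed in iNKT1-like and interferon-responding cells. Clusters with few UMIs per cell, weak markers or markers of 2 classes stayed unnamed. Cell classes rebuilt in this way may differ from those of the study.

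Raw counts were summed per library over all kept cells and over the cells of each class with at least 20 cells in every library, since cells are not replicates. The sums were tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, group as the only term) with Benjamini-Hochberg adjustment over all genes tested, at 0.05. CPM values are TMM-scaled unless stated. Percents and ratios of marker levels between classes use CPM without scaling factors. This test gives no standard error, so SE stands for the absolute log2 fold change divided by the square root of its F statistic. The difference between strain effects in iNKT1-like and iNKT2-like cells was an interaction term over 8 sums with the library as a block. Gene lists fixed before the data were examined (with at least 4 tested genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, over 26, 22 and 23 lists in all, iNKT1-like and iNKT2-like cells; no call at the preset correlation held with an estimated correlation. Shares were compared by exact two-sided permutation, and each share has an exact 95% binomial interval that covers counting error only. A cell's Trbv segment was its most abundant one, with at least 2 UMIs and no tie.

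The rule for named genes, set before the data were examined, took for each list up to 4 members of lowest p, a fixed set with Zbtb16, Tbx21, Gata3, Il4, Ifng and Il17a where tested, and per comparison the 10 genes with the largest change in each direction among those called, at a mean of 20 CPM or more and with groups that do not overlap. It skipped TCR and immunoglobulin segments, H2 genes, sex-linked genes and predicted genes; 137, 79, 186 and 57 such calls in all, iNKT1-like, iNKT2-like and iNKT17-like cells were counted but not named. Some genes that meet this rule are not reported here. For the interaction it took the 5 genes of lowest p in each direction. A fold against a strain with 0 UMIs was computed against a floor of 3 counts over the group. The 95% intervals of count ratios cover counting error only, not the spread between libraries.

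The tests were checked on simulated counts with known changes (dispersion 0.01). This is smaller than the spread between the B6 libraries, whose log2 ratio had an SD of 0.553 over genes, against 0.174 for the BALB/c pair. Simulated genes also varied independently of each other. Recovery in the real data may thus be lower than given here. Of genes changed 2-fold, edgeR recovered 86.6% over all cells, 68.7% in iNKT1-like, 70.1% in iNKT2-like and 58.2% in iNKT17-like cells, and 50.7% for the interaction; of genes changed 1.5-fold over all cells it recovered 50.7%. A simulated list with every member raised 2-fold had adjusted p = 0.0968 with an estimated correlation, so that setting has little power with 4 libraries. The fry test gave the same list an adjusted p = 0.00221, and of the real lists it called 0 in all, 0 in iNKT1-like and 13 in iNKT2-like cells.

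Alternatives set before the data were examined were DESeq2 1.42.0, RLE scaling, other filters on low counts, glmTreat against a fold of 1.5, thinning to equal totals, the replicate number as a block, leaving out each library, doublets kept, all deposited barcodes, other Leiden resolutions, integration with Seurat 5.3.0 and assignment of each cell to its highest marker score. Chosen after seeing the data were the first 2 naming rules, a limit to genes with at most 2000 bases of intron, and a crossed pairing of replicate numbers. All Xist counts were high (510, 484, 365 and 326 CPM) and Ddx3y was at 0 to 0.027 CPM in BALB/c 1, BALB/c 2, B6 1 and B6 2. These values are without scaling factors. Analyses ran in Python 3.11.15 and R 4.3.3. The BALB/c genome sequence was not used here.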

Results

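Invariant natural killer T (iNKT) cells are T lymphocytes that recognise lipids on the antigen-presenting molecule CD1d through a largely invariant TCR alpha chain. They leave the thymus as functional subsets named by their transcription factors and cytokines: iNKT1 (Tbx21, Ifng), iNKT2 (Zbtb16, Il4) and iNKT17 (Il17a). Here thymic cells that stained for CD3 and for CD1d loaded with the glycolipid PBS57 were profiled by droplet-based 5' single-cell RNA sequencing in 2 inbred mouse strains, BALB/c and B6, with 2 libraries per strain. The files held 2038 and 2056 barcodes for BALB/c 1 and 2, and 2494 and 9732 for B6 1 and 2. Total UMI counts were 23124810, 22798414, 20406245 and 82904358, and filtering kept 1864, 1913, 2328 and 8790 cells. Median UMIs per kept cell were 11004, 9131, 7016 and 6923 in the same order. The labels do not say whether the libraries of a strain came from separate mice, so the spread between them may be partly technical. The B6 libraries lay farther apart than the BALB/c libraries, with a chi-square per degree of freedom of 103.1 across genes against 8.66. Strain differences are given as BALB/c relative to B6 throughout.

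The first comparison asked how the iNKT subsets were represented in each strain. iNKT1-like cells, which carry NK-cell receptors and cytotoxic granule genes, were 15.1% and 31.8% of kept cells in BALB/c and 57.4% and 51.4% in B6 (23.5% ± 11.8 against 54.4% ± 4.21, SD, n = 2). iNKT2-like cells, the class with the most Il4 per cell of these 3, were 43.0% and 33.3% in BALB/c and 4.47% and 10.1% in B6 (38.2% ± 6.88 against 7.29% ± 3.99). iNKT17-like cells, defined by Il23r, Blk and Il1r1, were 17.1% and 9.51% in BALB/c and 2.96% and 1.95% in B6 (13.3% ± 5.37 against 2.46% ± 0.72). The strains did not overlap in any of these shares, and the differences were -31.0, 30.9 and 10.9 percentage points. An exact two-sided permutation test gave p = 0.333 for each, the smallest value that 2 against 2 libraries allow. All libraries were sorted on CD3 and CD1d, though 41 kept cells formed a B cell cluster. The iNKT1-like and iNKT2-like clusters were mostly of 1 strain. Clusters 0, 2, 3 and 4 held the B6 iNKT1-like cells and clusters 10 and 11 those of BALB/c. Cluster 1 held BALB/c and cluster 5 B6 iNKT2-like cells. Another 8.58%, 3.03%, 15.5% and 20.5% of cells in BALB/c 1, BALB/c 2, B6 1 and B6 2 stayed unnamed, and double-positive thymocyte-like cells made up 4.72%, 8.26%, 4.98% and 2.48%.

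The rule that named clusters was the last of 3, and was chosen with the shares already in view; under the first, the iNKT1-like difference was -41.9 points. The iNKT2-like difference was 7.49 points at a Leiden resolution of 1.5 and 8.52 after integrating the libraries. It was -9.40 points under the second rule with all deposited barcodes, when 59.7% and 47.6% of the BALB/c barcodes were left unnamed.

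**Figure D1:**
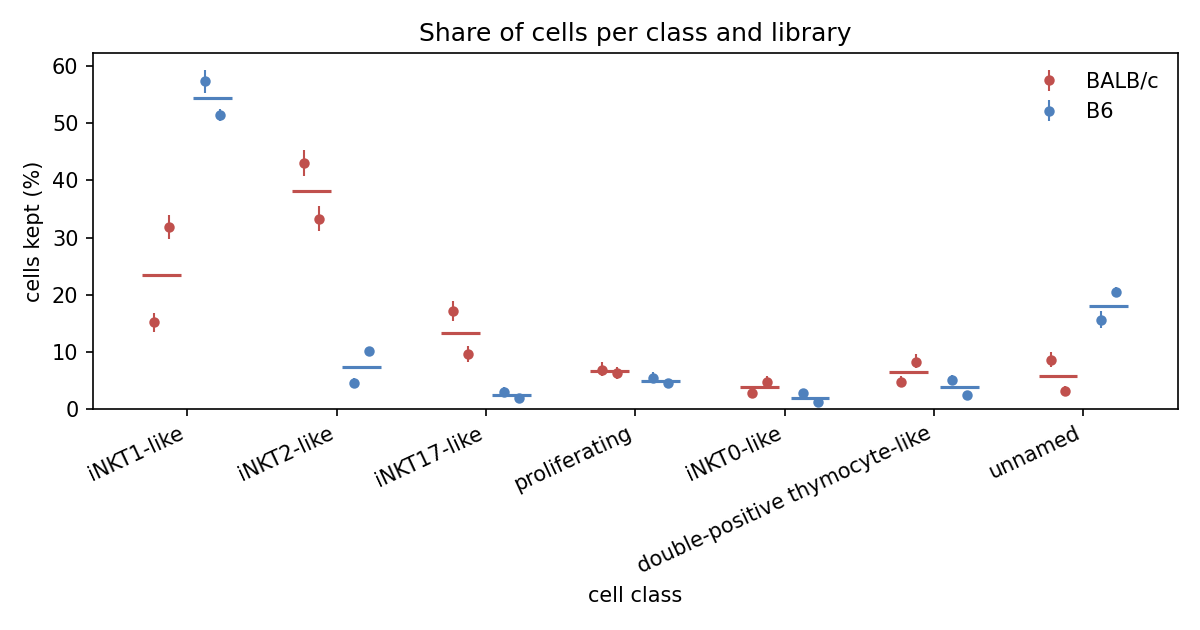
Percent of kept cells (y axis) in the main classes (x axis) for each library, with BALB/c in red and B6 in blue; points are libraries with 95% exact binomial intervals, and horizontal bars are strain means. Both B6 libraries, at 57.4% and 51.4%, lie above both BALB/c libraries for iNKT1-like cells, and the order is the opposite for iNKT2-like and iNKT17-like cells.

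TCR beta chain use was compared next, because the invariant alpha chain pairs mainly with Trbv13, Trbv29 and Trbv1 segments. Trbv13 was the most abundant segment in 64.6% and 59.8% of BALB/c cells with a callable segment and in 63.6% and 67.6% of B6 cells. The difference of -3.43 points was about as large as the spread within strains (SD 3.40 and 2.88, n = 2; exact two-sided permutation p = 0.667). Counted over Trbv UMIs in place of cells, the difference was -6.24 points (exact p = 0.333). Trbv29 stood at 12.8%, 11.01%, 14.7% and 16.1% (-3.49 points, strains not overlapping, exact p = 0.333), and Trbv1 at 10.3%, 14.3%, 10.6% and 9.47% (2.26 points, exact p = 0.667). In double-positive thymocyte-like cells, which largely lack this bias, Trbv13 stood at 30.4%, 24.8%, 15.5% and 23.4%.

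The strains were then compared over all kept cells, by edgeR's quasi-likelihood test on UMI counts summed per library. Klrb1c (ENSMUSG00000030325, GRCm38 chromosome 6: 128778485 to 128789215), which encodes the NK1.1 receptor, was at 2.37 ± 0.49 CPM in BALB/c and 305 ± 14.9 in B6 (SD, n = 2; log2 fold change -7.01, SE 0.18, adjusted p = 0.0037). Tbx21, the lineage factor of iNKT1 cells, fell by 2.07 on the log2 scale (SE 0.27, adjusted p = 0.0308). The chemokine receptor Cxcr3 fell by 2.32 (SE 0.30, adjusted p = 0.0304). Il4, the signature iNKT2 cytokine, rose by 1.11 (SE 0.18, adjusted p = 0.0448), as did Il13 by 1.08 and the Th2-associated chemokine receptor Ccr4 by 1.68. Genes of iNKT17 cells rose too, among them the interleukin receptors Il1r1 by 1.94 and Il23r by 1.58 (adjusted p = 0.0297 and 0.0413). In all, 937 of 12878 genes passed an adjusted p of 0.05, 469 higher and 468 lower in BALB/c.

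By list, 8 of 16 measured iNKT1 markers fell, none rose and 8 did not pass over all cells (14 fell when adjusted over the list alone). These counts and the camera test include Klrb1c and Ly6c2, which were left out of naming as polymorphic between strains. Klrb1c also fell within iNKT1-like cells, so its fall need not reflect the share of these cells. Of 11 iNKT2 markers 4 rose and 7 did not pass (5 rose adjusted over the list alone). Of 14 iNKT17 markers 5 rose and 9 did not pass (11 rose adjusted over the list alone). Camera called all 3 lists with adjusted p = 1.86e-07, 0.00159 and 1.12e-05, against adjusted p = 0.695 with an estimated correlation for each. The cytotoxicity and NK receptor list had 8 of 21 members lower, among them Cd160 at -3.39, Hopx at -2.59 and Klre1 at -2.79 (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.99e-05, adjusted p = 0.695 with an estimated correlation). Of 39 interferon response genes 12 fell, 1 rose and 26 did not pass (23 and 2 adjusted over the list alone; camera adjusted p = 1.86e-07, adjusted p = 0.695 with an estimated correlation). They included the DNA-sensor family gene Ifi213 at -5.82, Ifit3 at -2.68 and Oas1a, which makes the activator of RNase L. Ifi213 also fell within iNKT1-like, iNKT2-like and iNKT17-like cells. In iNKT1-like cells the list as a whole did not fall (7 rose and 4 fell, median log2 change 0.151). That class leaves out the interferon-responding cluster, which held 2, 7, 112 and 656 cells of BALB/c 1, BALB/c 2, B6 1 and B6 2. Cells high in such genes, mostly of B6, were thus removed before that comparison. It therefore cannot decide whether the fall of Ifi213 reflects an interferon response. A strain difference at such genes alone was not tested apart. Oas1a had 0 UMIs in BALB/c and was at least 566-fold lower against a floor of 3 counts over the group. Cells of the interferon-responding cluster, named by genes of this kind, were 0.107% and 0.366% of kept cells in BALB/c and 4.81% and 7.46% in B6 (0.237% ± 0.183 against 6.14% ± 1.88, SD, n = 2; exact two-sided permutation p = 0.333). The mean shares were 2.07% and 4.89% after integrating the libraries. The overlapping list of 10 interferon-responding cell markers had 4 lower and 6 not passing (8 lower adjusted over the list alone; camera adjusted p = 0.000148, adjusted p = 0.695 with an estimated correlation). Among 32 loci known to be polymorphic between strains 13 fell and 4 rose (16 and 5 adjusted over the list alone; camera adjusted p = 0.00159, adjusted p = 0.77 with an estimated correlation).

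Broad metabolic lists moved little per gene over all cells. Of 89 genes matched as cytosolic ribosomal proteins 1 rose and 1 fell, the latter Rps18, with a median log2 change of 0.14 (0 and 1 adjusted over the list alone). The name pattern also takes in Rps6ka1, Rps6ka2, Rps19bp1 and Rps27l, which are not ribosomal proteins. Of 78 nuclear oxidative phosphorylation genes 2 rose (0 adjusted over the list alone), and of 13 mitochondrially encoded genes none passed either way. Of 18 glycolysis genes 1 rose, Pgam1 at 0.54 (3 rose and 1 fell adjusted over the list alone). Camera called these 4 lists higher with adjusted p = 0.00159, 0.000118, 0.0367 and 0.0424, against adjusted p = 0.695, 0.778, 0.695 and 0.695 with an estimated correlation. The glycolysis call was lost without B6 2 (adjusted p = 0.227). The gamma-delta T cell list had 2 of 5 members higher (3 adjusted over the list alone), Sox13 at 2.96 and the TCR gamma constant gene Tcrg-C4 at 0.93 (camera adjusted p = 0.00659, adjusted p = 0.695 with an estimated correlation). The TCR-induced early response list had 2 of 20 higher, the inhibitory receptor Pdcd1 at 1.49 and the immediate early factor Nr4a1 at 1.30, and 1 lower, Tnfrsf18 at -1.08 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0424, adjusted p = 0.695 with an estimated correlation). Camera called none of the lists for iNKT0 cells, proliferation, double-positive thymocytes, regulatory T cells, B cells, myeloid cells, transcription factors, cytokines, stress response, SLAM receptors, homing, cytokine receptors or cell survival over all cells, with adjusted p from 0.146 to 0.901. In the dissociation and stress list 4 of 21 genes rose, 0 fell and 17 did not pass (7 rose and 3 fell adjusted over the list alone). Single markers of other cells, picked out after their values were seen, ranged widely over the libraries. Without scaling factors, of B cell genes Cd79a stood at 0.54 to 34.1 and Ighm at 42.4 to 195 CPM. Of myeloid genes Lyz2 stood at 0.045 to 0.355 and Cst3 at 124 to 245 CPM, also without scaling factors.

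Large rises at 20 CPM or more over all cells were in Gfra4, a co-receptor of the GDNF family (43.5 ± 8.98 against 0.059 ± 0.083 CPM; log2 fold change 8.85, SE 0.48), Tpm3-rs7 (4.98), Ly6c1 (4.77), the inducible heat shock proteins Hspa1a (3.98) and Hspa1b (3.70), the peptide hormone gene Rln3 (3.31), the lysosomal protease Ctsl (3.07), Sox13 (2.96) and Prelid2 (2.96). Large falls at 20 CPM or more were in Trim12a, Klra9 of the Ly49 receptors (-8.95), the actin-binding coronin Coro2a (-8.46), Klrb1c, Ifi213, Styk1 (-5.00), the arginine deiminase Padi2 (-4.33), Apol7e (-4.04), Ly6c2 (-4.0) and Ly6a, the antigen Sca-1 (-3.49). Trim12a had 3 UMIs in BALB/c against 8168 in B6, a count ratio of 1297 (95% interval 444 to 6293). Tpm3-rs7, Rps18 and members of the Ly6, Klr, Apol and Trim families have close copies whose reads the counting could split. The reads of both strains were counted against a genome of B6 origin, so these values are uncertain. Hspa1a ranged widely between the BALB/c libraries (120 ± 62.4 CPM, against 7.72 ± 2.08 in B6). Zbtb16, the master factor of iNKT cells, was not called (log2 fold change 0.44, SE 0.39, adjusted p = 0.515), with 403 and 331 CPM in BALB/c and 170 and 372 in B6; without B6 2 its log2 fold change was 1.11 (adjusted p = 0.0105). Gata3 at 0.10 and Ifng at -0.63 were not called either (adjusted p = 0.462 and 0.164). Leaving out BALB/c 1 or BALB/c 2 left 0 genes (edgeR; 1400 and 1644 at an unadjusted p under 0.05), and leaving out B6 1 or B6 2 gave 5203 and 1784. There, 881 of the 937 were called in the same direction without B6 2. DESeq2 called 1747 genes on all 4 libraries, and the lone library left in a strain was assumed to vary like the other strain's.

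Within iNKT1-like cells, clusters 10 and 11 held the BALB/c cells and clusters 0, 2, 3 and 4 those of B6. The interferon-responding cluster 7, whose second marker class was iNKT1, is outside this comparison and held 2, 7, 112 and 656 cells of BALB/c 1, BALB/c 2, B6 1 and B6 2. The interferon-responding cells left out thus came mostly from B6. BALB/c iNKT1-like cells held more Ifng, the signature iNKT1 cytokine (83.8 ± 23 against 28.3 ± 1.33 CPM, SD, n = 2; log2 fold change 1.54, SE 0.20, adjusted p = 0.00858 by edgeR), and less Il4 (27.2 ± 2.67 against 57.3 ± 5.12 CPM; -1.09, SE 0.15, adjusted p = 0.0117). Ccl5, a chemokine of effector lymphocytes, rose by 2.07 and Csf1 by 1.98, while the T-box factor Eomes rose by 6.15 from 0.191 ± 0.023 to 13.9 ± 2.09 CPM. The make-up of the class differed between strains. Cluster 10, with Ccl5, Gzma and Klf2 among its leading genes, held 145 of 282 and 314 of 608 cells in BALB/c 1 and 2. Cluster 2, led by Gzma and Ccl5, held 310 of 1336 and 1080 of 4521 cells in B6 1 and 2. Whether this mix sets the differences in this class was not tested. Zfp683, which encodes the tissue-residency factor Hobit, fell by 1.47, and Tcf7, a factor of early T cells, rose by 0.94. Tbx21 itself was not called (-0.09, SE 0.13, adjusted p = 0.796), nor were Zbtb16 (-0.55) and Gata3 (0.10). In all, 272 genes were higher and 211 lower, of 10604 tested.

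The homing and tissue exit list had 6 of 21 members higher in BALB/c iNKT1-like cells and 15 not passing (12 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000398, adjusted p = 0.852 with an estimated correlation). These included the integrin subunit Itga4 (2.03), the thymic exit factor Klf2 (1.41) and the chemokine receptor Ccr2 (0.66). Klf2 is among the leading genes of cluster 10, so the unlike mix of clusters in the strains may enter here, which was not tested. The dissociation and stress list had 6 of 20 higher (7 adjusted over the list alone; camera adjusted p = 0.00464, adjusted p = 0.852 with an estimated correlation), led by the heat shock genes Hspa1a (4.37), Hspa1b (4.16), Hsph1 (1.65) and Dnaja1 (1.27). Hspa1a and Hspa1b also rose over all cells and in iNKT2-like and iNKT17-like cells. A part from dissociation of the samples was not tested apart from strain in any of these. Cytotoxicity and NK receptor genes went both ways, with 7 of 20 higher, among them Ncr1 (3.03) and the adaptor Tyrobp (1.64), and 4 lower, among them Cd160 (-2.15) and Klre1 (-0.85). Adjusted over the list alone 8 rose and 6 fell, and camera did not call the list (adjusted p = 0.392). Of 39 interferon response genes 7 rose, 4 fell and 28 did not pass (10 and 8 adjusted over the list alone; camera adjusted p = 0.252). Isg15 at 0.78 and Ifit1 at 1.04 were higher, and both turned to -0.38 and -0.56 when each cell was assigned to the class with its highest marker score. Camera called no other list in this class.

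Large rises in iNKT1-like cells were in Pianp, which had 3 UMIs in B6 (count ratio 691, 95% interval 234 to 3371), Ly6c1 (8.34), Tpm3-rs7 (5.08), the secretory chaperone Scg5 (4.99), Hspa1a, Hspa1b, Aldh7a1 (3.94), adenosine deaminase Ada (2.99) and Rln3 (2.14). Large falls were in Trim12a, which had 0 UMIs in BALB/c and was at least 178-fold lower, Coro2a (-8.12), Klra9 (-7.25), Klrb1c (-5.71), Ifi213 (-5.15), Ly6a (-4.04), Ly6e (-2.94), Styk1 (-2.90), Rps18 (-2.83) and the securin gene Pttg1 (-2.82). Without BALB/c 1 or BALB/c 2 the count fell to 32 and 0 genes (1081 and 1085 at an unadjusted p under 0.05 by edgeR), and without B6 1 or B6 2 it was 3357 and 1479. There, 476 of the 483 were called in the same direction without B6 2.

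In iNKT2-like cells, held mostly by cluster 1 in BALB/c and cluster 5 in B6, the BALB/c cells held less of the transcripts that mark iNKT1 cells and of interferon-induced genes. Nkg7, a granule membrane protein of cytotoxic cells, was at 7.68 ± 2.14 CPM in BALB/c and 110 ± 15.5 in B6 (SD, n = 2; log2 fold change -3.83, SE 0.20, adjusted p = 0.000565 by edgeR). Tbx21 fell by 2.39 (SE 0.25, adjusted p = 0.00448), Zfp683 by 3.58, Cxcr3 by 2.49 and Hopx by 6.53. The antiviral genes Oasl2 (-6.59), Isg20 (-1.29), Irf7 (-1.15) and Rtp4 (-1.05) fell as well, and Oas1a, with 0 UMIs in BALB/c, was at least 465-fold lower. Sox13, a factor of gamma-delta and IL-17-producing T cells, rose by 2.10 (SE 0.23, adjusted p = 0.00496). In all, 555 genes were higher and 768 lower, of 11416 tested.

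Of 15 measured iNKT1 markers 11 fell and 4 did not pass in these cells (14 fell adjusted over the list alone; camera adjusted p = 4.2e-10, adjusted p = 0.281 with an estimated correlation). The list again includes Klrb1c and Ly6c2, which are known to be polymorphic between strains. Its other members, like those of the other cell type lists, served to name clusters. Tests of these lists within a class thus depend on the naming. Of 39 interferon response genes 25 fell, 1 rose and 13 did not pass (30 and 1 adjusted over the list alone; camera adjusted p = 2.07e-12, adjusted p = 0.281 with an estimated correlation). The members of lowest p were Ifi213, Ifi206, Oasl2 and Oas1a. Of these, Ifi213, Oasl2 and Oas1a were also among those of lowest p in iNKT1-like cells, where camera did not call the list. Interferon-responding was the second marker class of cluster 5, with most B6 iNKT2-like cells (mean log2 fold 0.734, against 0.959 for iNKT2), and not of cluster 1. All 10 interferon-responding markers fell (10 adjusted over the list alone; camera adjusted p = 5.56e-07, adjusted p = 0.281 with an estimated correlation). Cytotoxicity and NK receptor genes fell in 9 of 15 cases (10 adjusted over the list alone; camera adjusted p = 2.35e-06, adjusted p = 0.281 with an estimated correlation). In the homing list 10 of 22 fell and 2 rose, with Ccr9 at -2.76, the egress receptor S1pr1 at -1.55 and Klf2 at -1.05 (12 and 2 adjusted over the list alone; camera adjusted p = 8.64e-05, adjusted p = 0.281 with an estimated correlation). Smaller lists were also called: 2 of 9 proliferation genes fell, Ube2c and Mki67 (2 adjusted over the list alone), 2 of 5 double-positive thymocyte genes fell (3), and 2 of 4 gamma-delta genes rose (4), with camera adjusted p = 0.0463, 0.00905 and 0.0134 and adjusted p = 0.394 with an estimated correlation for each. Ribosomal genes (2 of 89 higher and 2 lower; 1 and 2 adjusted over the list alone) and oxidative phosphorylation genes (3 of 78 higher; 0 adjusted over the list alone) were called higher by camera with adjusted p = 0.00133 and 0.0404, against adjusted p = 0.676 and 0.727 with an estimated correlation. Without B6 2 the camera calls of the proliferation, gamma-delta, ribosomal and oxidative phosphorylation lists were lost (adjusted p = 0.292, 0.157, 0.438 and 0.718), the last pointing down, and the double-positive thymocyte list was not tested. Camera called no other list in iNKT2-like cells. In the dissociation and stress list 7 of 20 genes rose, 1 fell and 12 did not pass (8 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.174).

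**Figure D2:**
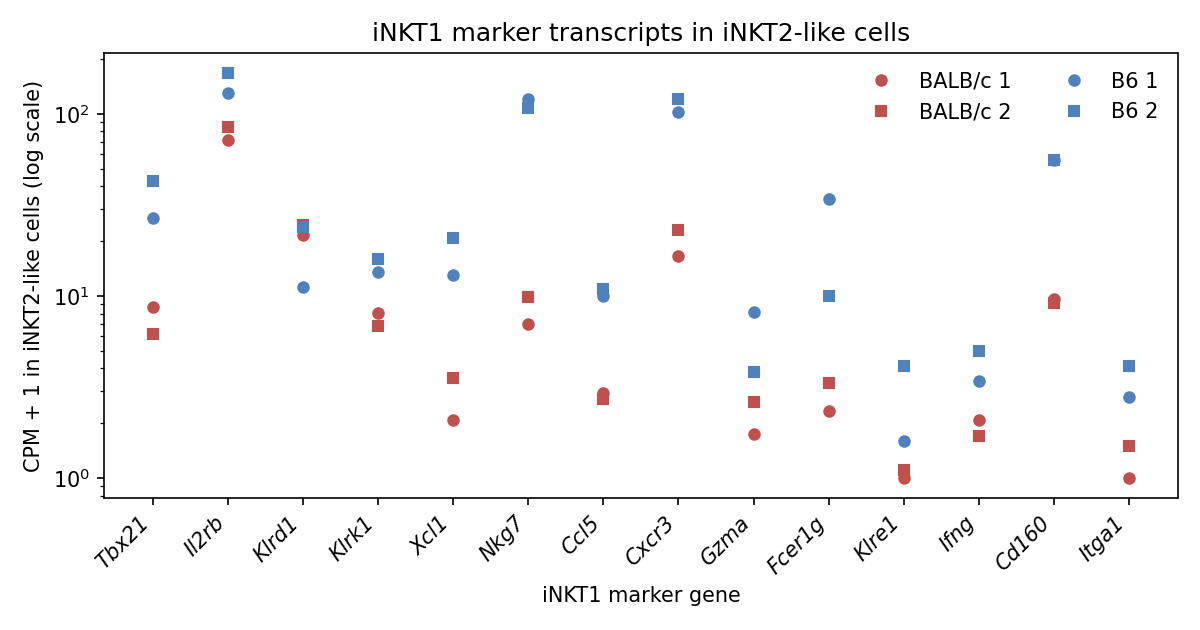
CPM without scaling factors plus 1 (y axis, log scale) of 14 iNKT1 marker genes (x axis) in iNKT2-like cells, 1 point per library, with BALB/c in red and B6 in blue. Nkg7 stood at 6.03 and 8.87 CPM in BALB/c 1 and 2 and at 119 and 107 in B6 1 and 2, without scaling factors.

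Of 11 iNKT2 markers 3 fell and 8 did not pass in iNKT2-like cells (4 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.968). These markers named the class, so this comparison is not independent of the naming. Plac8 (-1.36), Icos (-0.64) and Il17rb (-1.17) fell, while Il4 (0.38, adjusted p = 0.0597), Zbtb16 (-0.09, adjusted p = 0.862) and Gata3 (-0.27, adjusted p = 0.23) were not called. At a Leiden resolution of 1.5 the class held 249 and 229 BALB/c cells, against 802 and 637 here, and 78 and 615 B6 cells, against 104 and 889. An unnamed cluster there, with 312 and 210 BALB/c cells, had a mean log2 fold of -0.125 for iNKT2 markers. Whether the mix of cells in the class sets these differences was not tested. Ifng, at 0.731 to 3.73 CPM, was lower by 1.87 (adjusted p = 0.0348) and not called without B6 2. Other large rises were in Gfra4, with 0 UMIs in B6 and at least 197-fold higher, Tpm3-rs7 (5.36), Hspa1a (4.37), the Notch target Hey1 (4.0), Hspa1b (3.96), Rln3 (3.68), the cadherin Cdh13 (2.37) and the amyloid precursor gene App (2.14). Other large falls were in Trim12a, with 2 UMIs in BALB/c (count ratio 941, 95% interval 260 to 7777), Ly6c2 (-6.71), Ifi213 (-5.63), Ly6a (-5.54) and Padi2 (-5.18). The opioid receptor gene Oprm1 (-4.91) and Mir142hg (-4.46) rested on B6 2 alone, without which their log2 fold changes were -0.88 and -1.05 and not called. Leaving out BALB/c 1, BALB/c 2, B6 1 or B6 2 gave 165, 200, 5224 and 1667 genes, and 855 of the 1323 were called in the same direction without B6 2. B6 1 held only 104 iNKT2-like cells, and thinning every library to the lowest total left 443 genes; DESeq2 called 792.

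In iNKT17-like cells, all in cluster 8, Zbtb16 was at 345 ± 22.2 CPM in BALB/c and 356 ± 140 in B6 and was not called (SD, n = 2; log2 fold change -0.06, SE 0.23, adjusted p = 0.924 by edgeR). Il17a was at 0.276 and 163 CPM in BALB/c 1 and 2 and at 0 and 4.46 in B6 1 and 2, and was not called (adjusted p = 0.245). A single cell of BALB/c 2 held 355 of that library's 360 Il17a UMIs in this class, so the value of BALB/c 2 is that of 1 cell. Il4 (1.22) and Gata3 (-0.05) were not called (adjusted p = 0.222 and 0.904). Gfra4, Rln3 and the metalloprotease gene Adam33 had 0 UMIs in B6 and were at least 139-fold, 83.9-fold and 69.2-fold higher in BALB/c. In all, 226 genes were higher and 215 lower, of 9394 tested.

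Other rises in iNKT17-like cells were in Scg5, with 2 UMIs in B6 (count ratio 66.7, 95% interval 18.3 to 554), Hspa1a (5.77), Hspa1b (5.42), Tpm3-rs7 (5.29), the sodium pump regulator Fxyd7 (4.06) and the transcriptional co-repressor Cbfa2t3 (3.46). Falls were in Trim12a, with 0 UMIs in BALB/c and at least 103-fold lower, Ly6a (-7.15), Apol7b (-6.01), Ifi213 (-5.87), Klrb1c (-4.08), the kinase Galk2 (-3.99), the calponin Cnn3 (-3.97), Cd160 (-3.79), Ifi206 (-3.14) and Clec2i (-3.10). Without BALB/c 1, BALB/c 2, B6 1 or B6 2 the count was 322, 299, 1979 and 885, and 343 of the 441 were called in the same direction without B6 2. B6 1 held only 69 of these cells; thinning left 213 genes, and DESeq2 called 253.

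Whether the strain difference itself differed between iNKT1-like and iNKT2-like cells was tested by an interaction term with the library as a block. The cytokine gene Il4 had a strain difference of -1.09 in iNKT1-like and 0.38 in iNKT2-like cells, and the term for their difference was 1.5 on the log2 scale (SE 0.12, adjusted p = 6.41e-10 by edgeR). Nkg7 went the other way: its strain difference was 3.94 lower in iNKT2-like than in iNKT1-like cells (-3.94, SE 0.11, adjusted p = 3.19e-19), with 1773, 1769, 1719 and 1544 CPM in the iNKT1-like cells of BALB/c 1, BALB/c 2, B6 1 and B6 2. Ms4a6b (-2.28) and the survival GTPase Gimap3 (-3.50) followed Nkg7. The signalling chain of the TCR, Cd247 (1.44), followed Il4. In all, 1177 of 11994 genes differed, 489 with a higher and 688 with a lower strain difference in iNKT2-like cells. DESeq2 called 456, and without B6 2 the count was 507, of which 466 were shared with the same direction.

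Rps18, a ribosomal protein gene, stood at 533 ± 52.6 CPM in BALB/c and 3325 ± 10.4 in B6 over all cells (SD, n = 2; log2 fold change -2.64, SE 0.10, adjusted p = 0.00678 by edgeR). The predicted gene Gm10260, a near-copy of it, stood at 2671 ± 79.6 and 2.42 ± 1.52 (10.23, SE 0.60, adjusted p = 0.0117). Gm10260 lies outside the rule for named genes and was singled out after its values were seen. Without scaling factors, Rps18 and Gm10260 together gave 3201, 3116, 3300 and 3435 CPM in BALB/c 1, BALB/c 2, B6 1 and B6 2.

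**Figure D3:**
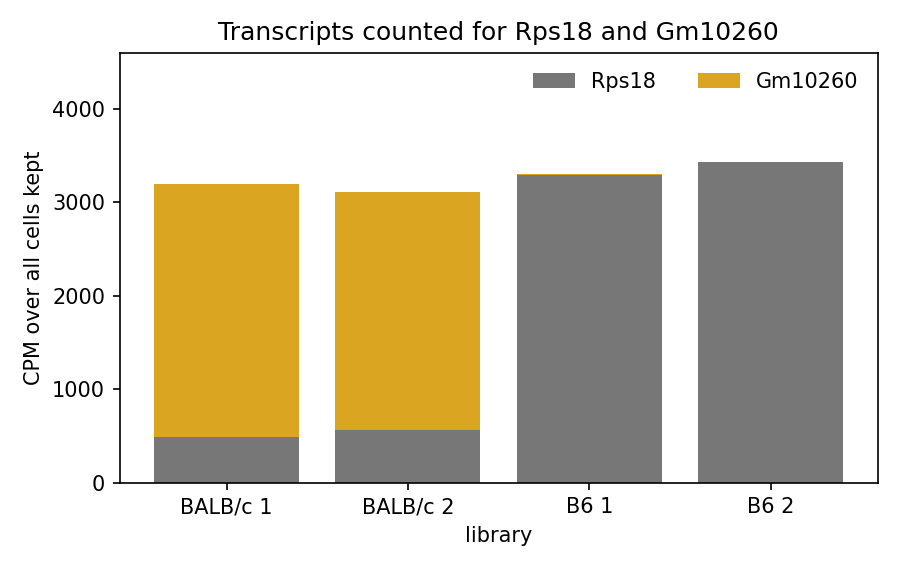
CPM without scaling factors over all kept cells (y axis) counted for Rps18 in grey and Gm10260 in yellow, stacked, for each library (x axis). The stacks reach 3201, 3116, 3300 and 3435 CPM, with most of the BALB/c counts in Gm10260 and nearly all of the B6 counts in Rps18.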

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

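All tests of the spread in iNKT1 marker percents, of the median cell and of gene copies, and the 2000-base limit on introns, were chosen after the results were seen. The interaction test was planned. The tests of free RNA by thymocytes, of marker UMIs per cell, of intron length, class shares and depth were set before their own values but after the patterns had been seen.

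The strain difference differed between iNKT1-like and iNKT2-like cells for 1177 genes by the planned interaction test (edgeR). The strain difference in iNKT2-like cells exceeded that in iNKT1-like cells on the log2 scale by 1.44 for Cd247, 1.21 for Ly6e, 1.11 for Rexo2, 1.5 for Il4 and 1.89 for Slc28a2. It lay below it for Nkg7 (-3.94), Ms4a4b (-2.26), Ly6c1 (-10.03), Gimap3 (-3.50) and Ms4a6b (-2.28). The lowest of these counts on leaving out a library was 507 genes, without B6 2.

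The first pattern weighed is the higher level of iNKT1 marker genes in B6 than in BALB/c iNKT2-like cells, which sits behind the negative term of Nkg7. If free RNA or iNKT1-like cells of the class profile were the only source, each abundant marker would stand at about the same percent of its iNKT1-like level. These percents ranged by 30.5 times or more within each B6 library, from 33.0% for Cxcr3 to 1.08% for Ccl5 in B6 1. In BALB/c iNKT2-like cells Il2rb stood at 8.2% and 10.2% and Ccl5 at 0.055% and 0.075% in BALB/c 1 and 2. The range was thus wide without the B6 excess too. The prediction leaves out any level that iNKT2-like cells hold themselves, so it cannot decide on either source. In B6 double-positive thymocyte-like cells the markers stood at a median of 0.5 times their iNKT2-like level in B6 2, at the bound set beforehand, and at 0.027 times in B6 1, so a part from free RNA stays open. The ratio of the median percents of the iNKT1-like level was 0.643 in B6 2 and 0.104 in B6 1. Several markers had no UMIs in the B6 1 thymocyte-like cells, so 0.027 lies near the floor. These B6 cells held a median of 2729.5 UMIs in their main cluster against 14016 in iNKT2-like cells of B6 2. Equal free RNA per droplet would thus give a ratio well above 1, so the bound was too lenient and 0.5 overstates such a part. The tenth of B6 iNKT2-like cells with the most marker UMIs held 42.4% of them in B6 1 and 37.5% in B6 2, against 20.6% and 20.7% if spread by depth, between the values set for and against a minority of iNKT1-like cells. In BALB/c 1 and 2, where the markers are low, the same fraction of cells held 44.5% and 45.3% (26.0% and 24.6% by depth). The median iNKT2-like cell held 5 marker UMIs in both B6 libraries and 1 in both BALB/c libraries, at similar depth, which argues against a minority of iNKT1-like cells as the only source. A part from such cells stays open. A strain difference within iNKT2 cells stays among the open explanations, as untested.

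The second pattern is the opposite change of Rps18 and Gm10260. The summed CPM of both genes differed between the strains by a log2 ratio of only -0.092, which is consistent with reads of 1 transcript being assigned to either copy. The longest reference transcripts of the genes, of 1151 bases for Rps18 and 561 for Gm10260, share 47.3% of the 25-base words of the shorter one. Other transcripts of the genes were not compared. A strain variant that makes BALB/c reads match Gm10260 better is a candidate cause that cannot be told apart here, because the BALB/c sequence was not used. A biological switch between the genes was not tested apart from this.

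The third pattern is the distance between the B6 libraries. Across 3073 genes, log2 of B6 2 over B6 1 rose with intron length (Spearman rho 0.513, against -0.101 for the BALB/c pair; genes are not independent replicates), which is consistent with intronic reads being counted in B6 2 only, the library whose header names the newer Cell Ranger. The SD of the log2 ratio was 2.998 times that of the BALB/c pair within iNKT1-like cells and 3.18 times with all libraries thinned to 1 total, which argues against shares of the named classes or depth as the cause. Within iNKT1-like cells B6 1 and B6 2 lay mostly in different clusters (21 and 1996 cells in cluster 0, 987 and 377 in cluster 3, 16 and 1068 in cluster 4), so a difference in the make-up of this class stays open. A biological or preparation difference between the B6 samples that favours long genes was not tested. Restricting the test to genes with at most 2000 bases of intron left 153 called genes of 1870 over all cells, against 937 of 12878 without the limit. Over all cells the share of tested genes called was thus not lower under the limit. In iNKT2-like cells it was lower, with 121 of 1539 against 1323 of 11416. It was similar in iNKT1-like (65 of 1366 against 483 of 10604) and iNKT17-like cells (50 of 1090 against 441 of 9394). A part of the calls from intronic reads thus stays open, above all in iNKT2-like cells.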

How the results depend on the processing

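The naming rules, the intron limit and the crossed pairing were chosen after the data were seen; all other settings were planned, except those of the interferon-responding share. Over the named genes, 2716 called values kept their direction and call, 544 kept the direction and lost the call and 3 reversed; of values not called, 191 stayed so, 27 became calls and 8 reversed. List members that were not called are left out of these counts, which was decided after their values had been seen. Over the called lists 136 values were kept, 62 lost and 1 reversed. Unless a cause is named, the cause was not tested. Leaving out a library leaves 1 in a strain, which is assumed to vary like the other strain.

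Over all cells the 937 genes became 1747 with DESeq2, 198 at a mean of at least 20 CPM, 264 with the replicate block, 246 with glmTreat and 1463 over the named iNKT classes only. With at most 2000 bases of intron, 153 of 1870 tested genes were called, against 937 of 12878. The 483 of iNKT1-like cells became 1341 with no filter, 195 at 20 CPM and 235 with glmTreat. With short introns it was 65 of 1366 tested genes, against 483 of 10604. The 1323 of iNKT2-like cells became 792 with DESeq2, 2955 with no filter, 385 at 20 CPM, 443 when thinned and 527 with glmTreat. With short introns it was 121 of 1539 tested genes, against 1323 of 11416. The 441 of iNKT17-like cells became 253 with DESeq2, 1112 with no filter, 204 at 20 CPM, 213 when thinned and 206 with glmTreat. With short introns it was 50 of 1090 tested genes, against 441 of 9394. The 1177 of the interaction became 456 with DESeq2. Leaving out 1 library gave 0 to 5203 genes over all cells, 0 to 3357 in iNKT1-like, 165 to 5224 in iNKT2-like and 299 to 1979 in iNKT17-like cells and 507 to 1295 for the interaction; each low value comes without a BALB/c library except for the interaction, where it comes without B6 2.

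The 13, 2 and 10 lists called in all, iNKT1-like and iNKT2-like cells became 0, 0 and 0 with an estimated correlation, and 0, 0 and 13 with fry; leaving out 1 library gave 11 to 14, 2 to 5 and 5 to 11. The nuclear oxidative phosphorylation list in iNKT2-like cells turned down without B6 2 (adjusted p = 0.718), and leaving out 1 library gave it an adjusted p of 1.14e-06 (without B6 1) to 0.718.

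The labels do not say whether libraries of the same number share more than that number. Deviations of the libraries numbered 1 minus 2 correlated between strains at -0.234 over all cells. They correlated at -0.006 in iNKT1-like, -0.010 in iNKT2-like and 0.002 in iNKT17-like cells. The B6 deviation rose with intron length (rho 0.513 for B6 2 over B6 1), which can hide a shared part, so a pairing is not excluded. With the replicate block 577, 1410 and 547 genes were called in those 3 classes. It called 10, 3 and 9 lists in all, iNKT1-like and iNKT2-like cells. The crossed pairing called 788 genes over all cells.

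The iNKT1-like share difference of -31.0 points was -21.3 by highest marker score, -41.9 under the first naming rule, -41.9 under it at Leiden resolution 1.5, -44.7 under it with doublets kept and -21.9 under the second rule with doublets kept. The iNKT2-like difference of 30.9 points was 18.6 by marker score, 7.49 at Leiden resolution 1.5 and 8.52 after Seurat integration, under each naming rule; at resolution 1.5, 36.6% and 22.9% of BALB/c cells were unnamed. It reversed to -9.40 under the second rule with all deposited barcodes. Without 1 library the differences were -39.3 to -22.6 for iNKT1-like, 26.0 to 35.7 for iNKT2-like, 7.06 to 14.7 for iNKT17-like cells and -5.84 to -1.03 for Trbv13. The interferon-responding share and all its settings were added after the data were seen. Its difference of -5.9 points was -3.27 with all deposited barcodes, -7.66 at Leiden resolution 0.5, -2.82 after Seurat integration and -9.30 by marker score. The first rule gave -3.27 with all deposited barcodes and -2.82 after integration, and the second rule the same and -7.66 at resolution 0.5. Without 1 library it was -7.23 to -4.57.

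Reversed log2 values of single genes were these. By marker score, Ifit1, iNKT1-like cells, was -0.56 and Isg15, iNKT1-like cells, -0.38; under the first naming rule Ramp1, iNKT1-like cells, was -0.034. Leaving out 1 library gave Zbtb16, all cells, -0.009 (without B6 1) to 1.115 (without B6 2), Zbtb16, iNKT2-like cells, -0.409 (without B6 1) to 0.375 (without B6 2) and Zbtb16, iNKT17-like cells, -0.402 (without B6 1) to 0.417 (without B6 2), with 0.016 without BALB/c 1. It gave Tbx21, iNKT1-like cells, -0.195 (without B6 1) to 0.019 (without BALB/c 2), with 0.0 without B6 2, and Gata3, iNKT17-like cells, -0.168 (without B6 2) to 0.046 (without B6 1). Gata3, iNKT17-like cells, was 0.169 when thinned. B6 1 held 104 iNKT2-like and 69 iNKT17-like cells.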

Other observations

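The counts of cytokine UMIs per cell were chosen after the Il17a value of BALB/c 2 had been seen. In iNKT2-like cells Il4 was found in 79.7% and 84.1% of BALB/c cells and in 80.8% and 77.2% of B6 cells, against 0 of 88, 0 of 158, 0 of 116 and 3 of 218 double-positive thymocyte-like cells of BALB/c 1, BALB/c 2, B6 1 and B6 2. Il13 was found in 14.7%, 20.4%, 22.1% and 20.8% of iNKT2-like cells. In iNKT1-like cells Ifng was found in 36.2% and 29.8% of BALB/c and 12.7% and 15.7% of B6 cells, and Il4 in 13.5% and 12.3% of BALB/c and 26.3% and 30.6% of B6 cells. Median UMIs per iNKT1-like cell were 6479, 6772, 7142 and 6868, so depth was alike there; in double-positive thymocyte-like clusters it was lower. These shares were not thinned to 1 depth and have no test.

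Il17a, the cytokine that names iNKT17 cells, was found in few cells of the class, though a cell with 0 UMIs can still hold the transcript: 1 of 319, 3 of 182, 0 of 69 and 9 of 171 iNKT17-like cells had a UMI in BALB/c 1, BALB/c 2, B6 1 and B6 2. One cell of BALB/c 2 held 355 UMIs, 98.6% of the library's Il17a in that class. Of the Il4 UMIs in iNKT17-like cells, 11.3%, 15.6%, 31.7% and 12.9% were in 1 cell in the same library order.

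The Trbv13 share stood at 70.8%, 70.1%, 71.2% and 72.2% in iNKT1-like cells and at 69.1%, 59.3%, 58.3% and 62.4% in iNKT2-like cells of BALB/c 1, BALB/c 2, B6 1 and B6 2. iNKT17-like cells stood at 72.5%, 77.1%, 71.6% and 73.2%. Proliferating cells made up 6.87%, 6.22%, 5.37% and 4.45% of the kept cells, and iNKT0-like cells, an early stage, 2.79%, 4.65%, 2.71% and 1.23%.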
